A study of Mus musculus with 3 samples.

How the data were processed

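NELF-A, a subunit of the negative elongation factor complex that holds RNA polymerase II near the start of genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hearts of male C57BL/6 mice aged 12 weeks. There were 3 sequenced libraries: 1 NELF-A library from sham-operated hearts (Sham), 1 NELF-A library from hearts after transverse aortic constriction (TAC), and 1 Input library of chromatin pooled from both kinds of heart. TAC narrows the aorta and loads the left ventricle with pressure, and per the labels' protocols hearts were taken 4 to 7 days after it. The labels name 3 mice for each NELF-A library. How their chromatin was combined is not given in the sources used here. The title of the TAC library and the words for enlarged hearts in its treatment label put it in the TAC group, while the same label also names sham surgery. Per the file headers, the deposited columns name the libraries Sham2 and TAC2, where the titles have Sham and TAC, and the sources used here do not say what the added 2 stands for.

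A contract laboratory made the libraries and the signal values. The submitters' processing notes name BWA, SICER and the mouse build mm10, with no versions. The run settings deposited with the tables name MACS with a p of 1e-07 as the peak caller, the pooled Input as control, tags of 75 bases, fragments of 200 bp and bins of 32 bp. Both peak callers are therefore reported, and which of them made the final peak list is not settled by the files. Per the file headers, the NELF-A signal is a mean tag density per bin, over a 2000-bp promoter window, a gene body window or a merged region, and the maximum over a region is also given. The deposited peak counts are whole numbers of peaks per chromosome and of merged regions with a peak in either library or in both. The authors' deposited ratio columns give TAC over sham for NELF-A and for RNA polymerase II. The authors' NELF-A ratio equalled the TAC signal over the Sham signal in all 13805 rows where both could be computed, with a largest difference of 4.44e-16. The RNA polymerase II ratios come from libraries outside this series, and only these authors' ratios were used. The tables hold 14 further columns of single libraries beside the genes and 4 beside the regions that belong to no sample here, and none was used.

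The table of genes held 26735 rows, besides 3 rows that name no gene. The promoter with the highest summed Sham and TAC signal was kept for each symbol, which left 26704 genes. Gene starts were compared with RefSeq positions on GRCm38, the same build as mm10, and coordinates are given as the files give them. Region lengths in the files equal end less start, so whether region starts count from 0 or 1 is open by 1 bp. The body window was the gene length less 1000 bp in 23046 rows.

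The deposited bin totals were 1.04e+08 in both NELF-A libraries, so their depths had been made equal before deposit, and the depth before that is not given in the sources used here. Whole bin sums, within 0.02 bins, made up 98.1% of promoter rows in Sham and 98.4% in TAC when the mean was multiplied by 63 bins. Among promoters with few tags, 71.8% of bin sums in Sham and 69.6% in TAC were multiples of 7, against 14.3% by chance. A fragment was therefore counted as 7 bins, which gives 14792622 fragments in each library. On that basis each TAC/Sham ratio has an exact (Clopper-Pearson) 95% interval. These intervals cover counting error only, since fragments were amplified and carry no molecular identifiers, and they say nothing about the spread between mice.

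With 1 library in each group there is no replicate check, no test and no p-value. Changes are log2((TAC + 1)/(Sham + 1)), which understates the change of low promoters. A promoter counted as occupied at or above the 95th percentile of Input over the same promoters, 4.25 tags per bin, and changes were counted at 1.5-fold among promoters occupied in either library. Regions have no Input column, so the promoter floor stood in for theirs, which departs from the plan. In the region table a promoter spans -7500 to 2500 bp around a gene start and a CpG island counts within 200 bp, per the run settings deposited. Only regions with a NELF-A peak were used, because the region table was merged over 6 ChIP libraries, 4 of them with other antibodies. The median of each of 21 gene lists is given with its binomial (order statistic) 95% interval over genes. It is also given as a percentile among 10000 random lists of the same size matched on signal in 20 bins, as a description of these libraries. RNA polymerase II medians of NELF-A classes were set against random sets matched the same way. Counting error was simulated by 1000 Poisson draws with no change between libraries. Shares of regions have Wilson intervals.

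The lists, the thresholds and the rule for naming genes were set before the data were examined. The rule takes the 10 highest and 10 lowest changes among promoters at 2 times the floor or more, the 10 highest Sham signals, up to 4 extreme members of each list, 24 fixed genes and the 5 highest and 5 lowest regions. Unnamed gene models, microRNAs, small nucleolar RNAs and olfactory receptors were passed over. Of the genes that the rule names, 1 is not reported here. On simulated data for these 26704 promoters, the Sham against TAC comparison recovered 52.2% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 3-fold. It passed 0.353% of unchanged promoters above the floor. A true 1.5-fold change equals the threshold for a call, so the share recovered at 1.5-fold was largely set by construction. All changed genes had a mean signal at 2 times the floor or more, so recovery nearer the floor was not simulated. In simulated lists of 25 genes, 6.5% of unshifted lists fell outside the central 95% and 100% of lists shifted by 0.25 lay above it. These simulations held counting error alone, not the spread between mice or preparations.

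Alternatives were other fold thresholds, floors, pseudocounts and scalings, subtraction of Input, the gene body window and the region maximum. Added later were centring within signal bins, promoters with no other gene start within 2000 bp, regions merged over other libraries, and smooth muscle markers without Des and Abcc9. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.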

Results

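The series asked how NELF-A sits on promoters in the normal heart and in the heart enlarged by pressure overload. NELF-A was measured in 1 library from sham-operated hearts and 1 library from TAC hearts, with 1 pooled Input library as background. Each NELF-A library rested on 14792622 fragment equivalents. Values are mean tags per 32-bp bin over the 2000-bp promoter window, brackets after a TAC/Sham ratio give its exact 95% counting interval, and no value has a replicate check. Folds used to count promoters and regions, and log2 values, are on the log2(value + 1) scale.

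NELF-A occupied about the same number of promoters in both hearts. In Sham, 13552 of 26704 promoters (50.7%) reached the Input floor, and in TAC 13610 (50.97%), against 1339 (5.01%) in Input by construction. These shares rest on Input values as deposited, and the depth of Input was not compared with that of the NELF-A libraries. Both libraries occupied 13265 promoters, Sham alone 287 and TAC alone 345. The median signal of promoters occupied in either library was 43.9 in Sham, 42.5 in TAC and 2.81 in Input. The Spearman correlation of promoter signal between Sham and TAC was 0.981 across genes, which are not independent replicates.

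The 10 promoters with the highest NELF-A signals in Sham had similar signals in TAC. Ptma had 295.9 in Sham and 279 in TAC, and Ddx5, an RNA helicase, 287 and 283. Jun, a subunit of the AP-1 transcription factor, had 256 and 251, and its relative Junb 246 and 230. Hnrnpa2b1, D4Wsu53e, Klf10, Srsf2, Son and Herpud1 completed the 10 highest, and all 10 had TAC/Sham ratios between 0.902 (Klf10) and 0.998 (Son). The start of Ddx5 lies within 2000 bp of Cep95, that of Son of Gart, that of Srsf2 of Mfsd11 and that of Hnrnpa2b1 of Cbx3, so these windows overlap a second promoter.

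Genes of the pausing machinery and of the early stress response had similar NELF-A signals in both hearts. Nelfa itself (gene 24116, chromosome 5, 33898179 to 33936258) had 94.7 in Sham and 95.2 in TAC, a ratio of 1.01 (0.913 to 1.11). Hexim1, the inhibitor of the elongation kinase, had 154 and 141, and Cdk9, that kinase, 74.6 and 68.1. The list of 30 pausing and elongation genes had a median log2 of -0.045 (-0.097 to -0.013), with no member 1.5-fold apart, Larp7 highest at 0.17 and Aff4 lowest at -0.39. Among 30 immediate early and stress genes, none was 1.5-fold apart and the median was -0.0088 (-0.063 to 0.062), which turned to 0.028 when all promoters were centred on 0. Fosl1 was its highest member at 0.58, with 12.1 in Sham and 18.6 in TAC, and Jund its lowest at -0.30. Fos had 109 and 120, Egr1 78.1 and 72.7, Myc 57.2 and 64.3 and Atf3 152 and 152.

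Across promoters, NELF-A was at least 1.5-fold higher in TAC at 312 and at least 1.5-fold lower at 316, with 13269 of 13897 (95.5%) in between. Counting error alone gave a median of 19 in each direction, and at most 35 higher and 34 lower in 1000 draws. The median log2 TAC/Sham was -0.037 (-0.041 to -0.033), and centring on a median of 0 turned the split to 354 higher and 264 lower. Calls gathered at weak promoters: from 80 tags per bin upward, 2838 promoters held 0 higher and 5 lower calls, and between 1 and 2 times the floor 1502 promoters held 148 and 98. Direction differed with signal too. The median log2 was 0.028 between 1 and 2 times the floor, and between -0.048 and -0.026 in the groups of stronger promoters. Under the floor, 795 promoters were 1.5-fold higher and 421 lower, with a median of 0. The cause of this difference was not tested. At 2 times the floor or more, 164 were higher and 218 lower, against medians of 2 and 2 from counting error.

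**Figure D1:**
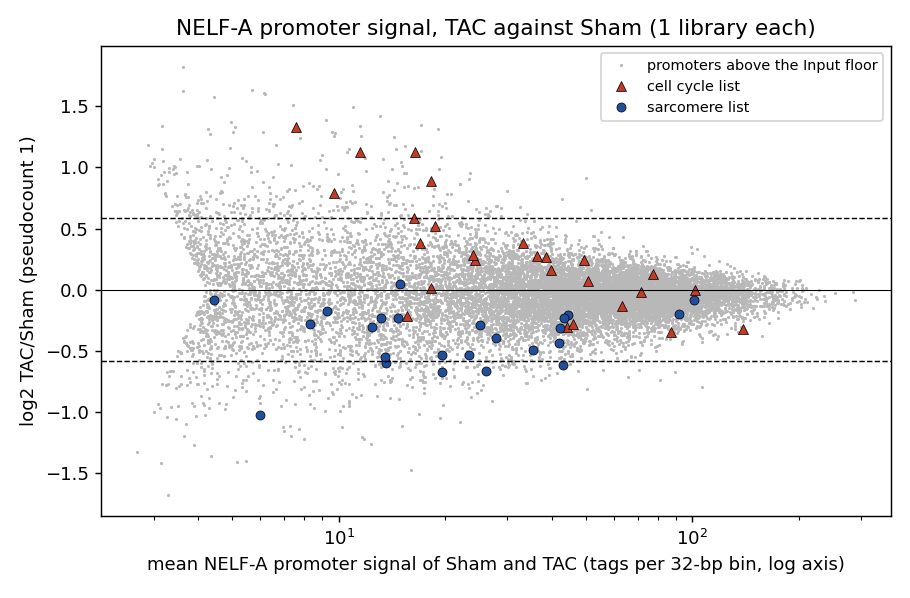
Each grey point is 1 of 13897 promoters above the Input floor, with the mean NELF-A signal of Sham and TAC in tags per bin on a log x axis and the log2 TAC/Sham on the y axis. Red triangles are the cell cycle list and blue circles the sarcomere list, dashed lines mark 1.5-fold, and 6 of the 26 triangles lie at or above the upper line while 5 of the 24 circles lie at or below the lower one.

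The 10 promoters with the highest NELF-A in TAC relative to Sham, among those at 2 times the floor or more, were led by Pbk. Pbk, a mitotic kinase (gene 52033, chromosome 14, 65805911 to 65817822), went from 2.27 tags per bin in Sham, close to its Input of 2.19, to 9.13 in TAC, a ratio of 4.02 (2.49 to 7.06). Ccnb2, a mitotic cyclin (chromosome 9, 70407689 to 70421554), had 5.27 and 16.7, a ratio of 3.16 (2.29 to 4.53). Bub1, a kinase of the spindle checkpoint (chromosome 2, 127800200 to 127831859), had 3.90 and 11.3, a ratio of 2.89 (1.97 to 4.41). Cit, the kinase of cytokinesis, had 6.65 and 19.5, and Fam83d, a spindle protein, 9.24 and 25.03. Neil3, a DNA repair glycosylase, had 2.54 and 9.79. Over gene bodies, with a median of -0.14 over all bodies above Input, Neil3 had a log2 of -0.15 and Tmem252 -0.17. The other 4 of the 10 highest were Tmem252 (2.56 and 9.81), the lipoprotein receptor gene Lrp8 (3.38 and 11.5), the glycosyltransferase gene Gcnt4 (4.67 and 13.8) and Mdfi (6.08 and 16.95).

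The 26 promoters of the cell cycle list were all above the floor, with 6 at least 1.5-fold higher in TAC, none 1.5-fold lower and 18 above 0. The list's median log2 was 0.24 (-0.0022 to 0.38), above every one of the 10000 matched random lists, whose central 95% ran from -0.14 to 0.047. Bub1 stood at 1.33 and Cdk1, the kinase that drives mitosis, at 1.13 (9.95 in Sham and 22.9 in TAC). Ccnd2, a cyclin of the first gap phase, was lowest at -0.35 (97.3 and 76.2), followed by the cell cycle inhibitor Cdkn1b at -0.32 (154 and 123). Over gene bodies, 8 bodies of the list lay above their Input floor and had a median of -0.21, against -0.14 over all 3993 such bodies. Macrophage and leukocyte markers had a promoter median of 0.14 and fibroblast markers 0.044.

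Promoters in 4 lists of cardiomyocyte genes, each read as a set, had less NELF-A in TAC. The sarcomere list had a median log2 of -0.31 (-0.54 to -0.23), with 23 of 24 members below 0, 5 at least 1.5-fold lower and none 1.5-fold higher. Cardiac transcription factors had -0.33 (-0.52 to -0.22), with 22 of 24 below 0 and 4 at least 1.5-fold lower. Calcium handling and ion channel genes had -0.25 (-0.49 to -0.083), with 20 of 24 below 0 and 4 at least 1.5-fold lower. Fatty acid oxidation genes had -0.24 (-0.33 to -0.11), with 26 of 26 below 0 and 1 at least 1.5-fold lower. All 4 medians lay at percentile 0 of their matched random lists. Over gene bodies the cardiac transcription factors had -0.18, over 10 bodies above their Input floor. Smooth muscle and pericyte markers had a median of -0.35, or -0.15 at percentile 14.7 without the 2 members that cardiomyocytes also express, while endothelial, fibroblast and leukocyte markers had -0.059, 0.044 and 0.14.

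Myom2, a protein of the sarcomere M band, had 8.41 in Sham and 3.62 in TAC, a ratio of 0.430 (0.279 to 0.661). Myl2, the ventricular regulatory light chain, had 24.4 and 14.9, a ratio of 0.612 (0.490 to 0.762), while Myom1 had 14.7 and 15.2. Among transcription factors, the ventricular factor Irx4 had 18.5 and 9.51 and Tbx5 had 12.6 and 6.60, whereas Nfatc2 (18.7 and 20.4) and Tead1 (47.3 and 49.7) lay slightly above 0. Kcnip2, a subunit of the transient outward potassium channel, had 16.7 and 6.67, a ratio of 0.3996 (0.291 to 0.543), and the potassium channel gene Kcnh2 had 31.0 and 16.4. Cacnb2, a calcium channel subunit, went the other way with 12.0 and 16.0. Ppargc1a, the coactivator of mitochondrial genes, had 14.4 and 8.29, and Ppara, the nuclear receptor for fatty acids, 78.4 and 52.3. Hadha and Hadhb, whose promoter windows overlap, had ratios of 0.988 and 0.990. Myh6 (14.4 and 12.0), Atp2a2 (70.0 and 64.5) and Cpt1b (27.6 and 20.03) were within 1.5-fold.

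The 10 lowest promoters among those at 2 times the floor or more were led by Ppl, which encodes periplakin (gene 19041, chromosome 16, 5086291 to 5132481), with 24.1 in Sham and 8.02 in TAC, a ratio of 0.333 (0.251 to 0.435). Besides Kcnip2, they held the sodium channel subunit gene Scn4b (17.9 and 6.87) and Kcnd3, the pore-forming partner of Kcnip2 (14.4 and 6.06). Sgca, a sarcoglycan of the muscle membrane, had 21.1 and 9.22. Crhr2, a urocortin receptor, had 10.6 and 4.08. Clec3b (11.6 and 4.40), the ephrin gene Efnb3 (16.9 and 6.67) and the interferon-induced GTPase gene Iigp1 (10.98 and 4.43) were the others reported here. Efnb3 and Crhr2 turned to 0.13 and 0.0048 on the log2 scale over gene bodies.

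Some markers of cardiac hypertrophy had more NELF-A in TAC. Of 28 above the floor, 4 were at least 1.5-fold higher in TAC and none lower, with a median log2 of 0.012 (-0.14 to 0.22) at percentile 75.4. Acta1, the skeletal actin of the fetal gene program, had 2.03 in Sham and 6.54 in TAC, a ratio of 3.22 (1.91 to 5.91) from 18 and 59 fragment equivalents, but -0.47 on the log2 scale over its gene body. Timp1, an inhibitor of matrix proteases, had 2.67 and 7.17. Xirp1 (23.8 and 16.6) and Synpo2l (13.9 and 9.79) were the lowest. The natriuretic peptide genes showed little: Nppb had 14.7 and 14.7, and Nppa 3.29 and 4.49, a ratio of 1.37 (0.810 to 2.22), not distinguishable at this depth. Myh7 (4.51 and 4.02), Ankrd1 (7.52 and 6.67), Ctgf (64.9 and 56.4), Rcan1 (34.7 and 29.0), Vim (146 and 161) and Hmox1 (31.3 and 40.5) were within 1.5-fold.

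Extracellular matrix genes had a median log2 of 0.0030 (-0.16 to 0.30), with 2 of 28 at least 1.5-fold higher in TAC. These were Tnc, a matrix protein of wounds, and Postn, a product of activated fibroblasts. Tnc had 1.05 in Sham, below its Input of 2.13, and 6.22 in TAC. The ratio of Tnc was 5.94 (3.05 to 14.3), from 9 and 56 fragment equivalents. Postn had 4.84 and 8.78, a ratio of 1.81 (1.23 to 2.66). Col1a1 had 40.7 and 37.9, Tgfb2 31.4 and 24.5, and Dcn 4.89 and 3.52. Inflammation genes, beside the leukocyte marker median of 0.14, had a median of 0.11 (-0.044 to 0.34) at percentile 99.9, with 4 of 24 at least 1.5-fold higher. At 2 times the floor the median was 0.034 over 17 genes. The cytokine gene Il6 had 1.95 and 5.19 and the chemokine gene Ccl7 3.83 and 6.78, while Cxcl12 (87.2 and 72.1) and Nfkb1 (50.5 and 42.0) were lowest.

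**Figure D2:**
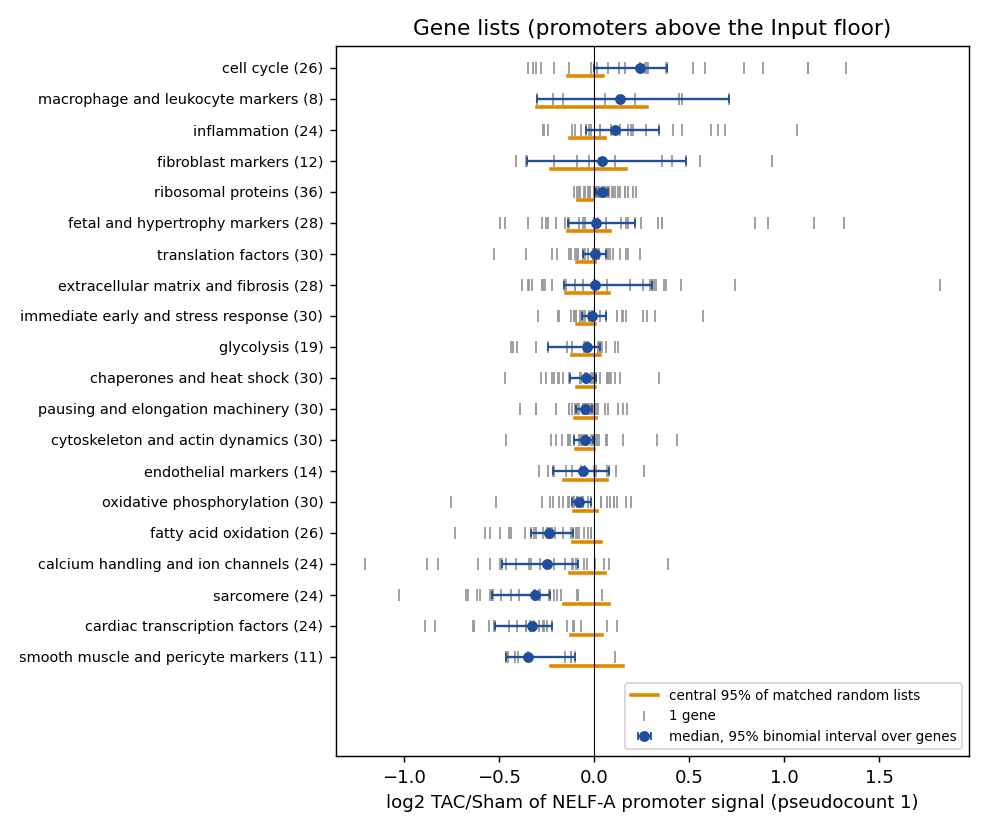
Log2 TAC/Sham of NELF-A promoter signal (x axis) for the gene lists with at least 6 promoters above the floor, whose number follows each name. Grey ticks are genes, blue points and bars are medians with 95% binomial intervals, and orange bars are the central 95% of matched random lists, from cell cycle at 0.24 down to smooth muscle and pericyte markers at -0.35.

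Lists of ribosomal proteins, translation factors, chaperones, the cytoskeleton, glycolysis and oxidative phosphorylation had medians between -0.077 and 0.041. Ribosomal protein genes had a median log2 of 0.041 (0.012 to 0.075) at percentile 99.99, with none of 36 members 1.5-fold apart, Rps4x highest at 0.22 and Rplp0 lowest at -0.10. Translation factors had 0.0035 (percentile 97.6), from Eef1a2 at -0.52 to Eif6 at 0.24. Chaperones had -0.042 (percentile 48.4, and 0.0013 centred within signal bins), from Hspb3 at -0.47 to Pdia6 at 0.34, and cytoskeleton genes -0.049 (percentile 39.1), from Tuba4a at -0.46 to Tubb2b at 0.43. Glycolysis genes had -0.039 (percentile 52.8), from Eno3 at -0.44 to Pfkp at 0.13. Oxidative phosphorylation genes had -0.077 (percentile 13.4), with 1 of 30 at least 1.5-fold lower, the muscle form Cox8b at -0.75 (31.3 and 18.2). Actb had 195 and 181 and Gapdh 199 and 192. Over gene bodies, where the median of all bodies above Input was -0.14, ribosomal proteins had -0.15 over 28 bodies, chaperones -0.22 over 15, translation factors -0.14 over 16 and glycolysis -0.19 over 16.

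Marker lists of other heart cell types had overlapping intervals. Smooth muscle and pericyte markers had a median log2 of -0.35 (-0.46 to -0.10) at percentile 0.07, with 10 of 11 below 0, and -0.15 at percentile 14.7 without Des and Abcc9, which cardiomyocytes also express. Kcnj8 (23.2 and 16.6) and Pdgfrb (33.3 and 23.9) were lowest and Smtn (70.8 and 76.6) highest. Endothelial markers had -0.059 (-0.21 to 0.081), from Pecam1 at -0.29 to Tie1 at 0.27. Fibroblast markers had 0.044 (-0.35 to 0.48), from Islr at -0.41 to Cthrc1 at 0.94 (1.84 and 4.44, but -0.074 over its gene body), and Thy1 had 8.57 and 13.1. Macrophage and leukocyte markers had 0.14 (-0.30 to 0.71), with 8 of 17 above the floor, C1qc highest (5.62 and 9.84) and Cd14 lowest (23.1 and 18.6). Of 32 genes of other organs, 28 lay under the floor, and the 4 above it included Cela1 (1.37 and 4.98) and Apoa2 (4.35 and 2.37).

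NELF-A peaks were shared between the hearts for the most part. The authors called 20459 peaks in Sham and 19599 in TAC, with 47.8% and 49.8% of them within 500 bp of a gene start. TAC had fewer peaks than Sham on 21 of 21 chromosomes, with ratios from 0.833 to 0.996. Merged over both libraries these made 21803 regions, of which 16913 had a peak in both, or 77.6% (77.01 to 78.1). Sham alone had 2787 and TAC alone 2103. In the region table merged over 6 ChIP libraries, regions with a peak in both held a promoter in 69.8% (69.1 to 70.4), against 24.8% (23.1 to 26.5) of regions in Sham alone and 26.2% (24.3 to 28.2) in TAC alone. CpG islands lay in 60.7%, 9.82% and 11.3% of them. Median lengths were 2774.5 bp for shared regions, 1598 bp for Sham alone and 1344 bp for TAC alone. The shares were not compared at equal length or signal. Regions of Sham alone had a median of 7.89 in Sham and 5.31 in TAC, and regions of TAC alone 5.55 and 8.09, against 22.8 and 21.9 in shared ones.

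Of 20926 regions with a peak and a signal above the floor, 972 were at least 1.5-fold higher in TAC and 1062 lower, and the median log2 was -0.050 (-0.054 to -0.047). Centring on a median of 0 turned this split to 1171 higher and 831 lower. Of 12679 regions with a promoter, 2.71% were higher and 2.90% lower, and of 8247 without one, 7.61% and 8.42%. The median Sham signal of these groups was 28.9 and 8.38, and the shares were not compared at equal signal. The highest region lay inside Tnr, 365852 bp from its start (chromosome 1, 159888649 to 159890593), with 1.78 in Sham and 10.95 in TAC. The next were at the starts of Neil3 (chromosome 8, 53638300 to 53639635, 3.62 and 14.8), AA467197 (chromosome 2, 122637579 to 122638565, 3.29 and 13.5), Pbk (chromosome 14, 65805346 to 65806759, 3.29 and 12.6) and Timp1 (chromosome X, 20869593 to 20870767, 2.97 and 11.2). The lowest lay inside Camkk2 (chromosome 5, 122760586 to 122761615), with 8.69 in Sham and 1.94 in TAC. It was followed by regions in 5830444B04Rik (at its start, chromosome 4, 155421029 to 155421855, 8.72 and 2.10), in the calcium pump gene Atp2b2 (chromosome 6, 113795037 to 113796026, 8.58 and 2.19), upstream of Dcxr (chromosome 11, 120728036 to 120728912, 10.7 and 3.15) and in Prrc2a (chromosome 17, 35158643 to 35159813, 9 and 2.83). Position relative to genes is that of the region table.

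The title of the series ties NELF-A on promoters to transcription, and the files allow its change to be set beside that of RNA polymerase II. Genes with higher NELF-A at the promoter in TAC had higher RNA polymerase II ratios in the authors' deposited table, and genes with lower NELF-A had lower ones. In the authors' deposited table, the median RNA polymerase II TAC/sham ratio in the gene body was 1.40 where NELF-A was at least 1.5-fold higher, 1.12 in between and 0.841 where NELF-A was at least 1.5-fold lower. Medians at the promoter in the authors' deposited table were 1.12, 0.724 and 0.653. Random sets matched on NELF-A signal had central 95% ranges of 0.995 to 1.11 (gene body) and 0.753 to 0.889 (promoter) for the first class, and of 1.02 to 1.13 and 0.735 to 0.839 for the last, from the authors' deposited table. The classes held 191, 12316 and 219 genes with a promoter ratio, and 181, 11516 and 201 with a gene body ratio. Genes without a ratio are left out, and these were a larger part of the changed promoters, which numbered 312 higher and 316 lower beside 13269 in between. Across all 12726 genes the relation was weak, with a Spearman correlation of 0.156 for the promoter and 0.189 for the gene body (11898 genes), computed across genes, which are not independent replicates. The promoter change of NELF-A and the RNA polymerase II ratio in the authors' deposited table lay on the same side of their medians at 54.7% of genes for the polymerase ratio of the promoter and at 55.7% for that of the gene body.

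**Figure D3:**
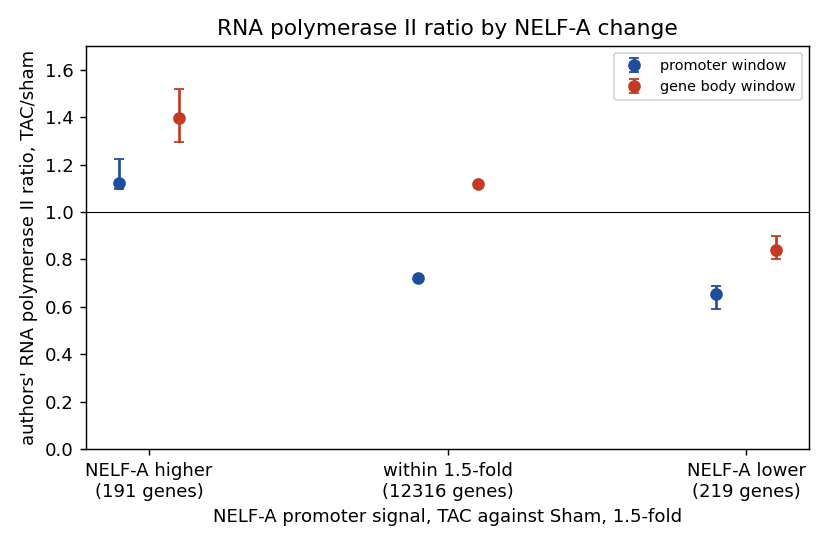
Median of the authors' RNA polymerase II TAC/sham ratio (y axis, linear from 0) at the promoter (blue) and in the gene body (red) for genes with NELF-A at least 1.5-fold higher, within 1.5-fold, or at least 1.5-fold lower in TAC. Bars are 95% binomial intervals of the medians over genes, the line marks a ratio of 1, and gene body medians run from 1.40 to 1.12 and 0.841.

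At single genes the ratios of NELF-A and RNA polymerase II differed in size and, at some, in direction. Nppb, with a NELF-A ratio of 1.001, had an RNA polymerase II gene body ratio of 32.1 in the authors' deposited table. Ankrd1, with a NELF-A ratio of 0.886, had 16.1 in the authors' deposited table, and Ctgf, with 0.868, had 8.44 there. Acta1, with a NELF-A ratio of 3.22, had 19.8 in the authors' deposited table, and Postn, with 1.81, had 12.5 there. In the authors' deposited table the sarcomere gene Myl2, with a NELF-A ratio of 0.612, had an RNA polymerase II gene body ratio of 1.57, and Kcnip2, with 0.3996, had 0.593. The median RNA polymerase II gene body ratio was 1.86 over the sarcomere list in the authors' deposited table, whose NELF-A median was -0.31 on the log2 scale. It was 3.19 over hypertrophy markers and 1.09 over cardiac transcription factors in the authors' deposited table.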

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

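The comparison of gene bodies with Input was chosen after the tables were seen, as a signal outside the promoters and regions compared above. More gene bodies reached a set Input level in the NELF-A libraries than in Input. Of 21509 bodies of at least 1000 bp, 3337 reached the Input 95th percentile of 3.73 tags per bin in both NELF-A libraries. In Input 1076 did, by construction. The median signal of the 3337 was 7.15 in Sham, 6.33 in TAC and 3.13 in Input. They were chosen by their NELF-A signal, so medians above Input follow in part from the choice. Signal from peaks at the gene start was not separated from signal further into the body. Of these bodies, 3015 also had a promoter above the floor in both libraries, and their median length was 6450 bp against 17003 bp over all bodies. NELF-A was at least 1.5-fold higher in TAC in 6 of them and lower in 93, with a median log2 of -0.13 (-0.14 to -0.12).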

How the results depend on the processing

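Centring within signal bins, promoters with no close neighbour, regions merged over 6 libraries and smooth muscle markers without Des and Abcc9 were added after the data were seen. Occupied promoters ranged from 13143 to 13824 in Sham and from 13165 to 13894 in TAC over Input percentiles 99 and 90, and all 8 alternative values of the RNA polymerase II comparison stayed within the interval of the main ones. Main counts were 312 promoters higher in TAC and 316 lower, and 972 and 1062 regions. Without a floor promoters came to 1107 and 737, with Input subtracted to 593 and 660, at 2-fold to 60 and 30, and in gene bodies to 18 and 133. At 2 times the floor 164 promoters were higher, and 604 and 653 regions were higher and lower. At the authors' cut-off of 0.75, 956 promoters and 2695 regions were lower. Regions came to 189 and 147 at 2-fold and to 1492 and 1736 by their maximum. The promoter median of -0.037 was 0 without a floor, -0.14 in gene bodies and -0.042 away from neighbours, and the region median was 0 by maximum. Regions with a peak in both libraries made up 79.1% when merged over 6 libraries. Floors, fold thresholds and cut-offs set by construction how many features are counted, and for the other settings the cause was not tested.

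Of 211 list values, 190 stayed within the interval of the list's median or equalled it. The 4 genes of other organs have no interval: their median of -0.028 was 0 without a floor, 0.19 at 2 times the floor (1 gene), 0.0092 centred, -0.038 centred within bins, 0.13 with Input subtracted, -0.045 and -0.015 with other pseudocounts, -0.095 in gene bodies and 0.15 as a mean. In gene bodies the median was -0.13 for oxidative phosphorylation, -0.083 for immediate early genes, -0.15 for pausing genes, -0.18 for cardiac transcription factors, -0.14 for translation factors, -0.22 for chaperones and -0.21 for the cell cycle. Ribosomal proteins reversed there to -0.15, close to the -0.14 of all bodies. A list counted as reversed only where the interval of its promoter median left out 0. Without that condition, signs also changed in gene bodies for the cell cycle (0.24 over promoters), translation factors, hypertrophy markers and endothelial markers. Centring put pausing genes at -0.0080 and ribosomal proteins at 0.078, and centring within bins at -0.0040 and 0.080. Of 775 values of 132 named genes, 674 stayed within the counting interval, and 84 of those that moved or reversed came from the gene body window. There, Efnb3 turned to 0.13, Crhr2 to 0.0048, Cthrc1 to -0.074, Tmem252 to -0.17, Neil3 to -0.15 and Acta1 to -0.47. The cause was not tested.

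Not run were Input subtraction for regions, which have no Input value, and stricter overlaps or scores of peaks, which are not listed for each library here. Limiting the RNA polymerase II comparison to the authors' subset is the main setting, since ratios exist only there. No paired analysis was possible because each group has 1 library, so no library was left out either. Depth limits promoters near the floor: at Nppa, with 4.49 in TAC, the counting interval of the ratio ran from 0.810 to 2.22.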

Other observations

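The tests of enrichment over background, leukocytes and cardiomyocyte share were chosen after the results they bear on were seen, while the others were set down before. Read as 1 list, promoters of further genes of mitosis and DNA replication had more NELF-A in TAC. A second list of 61 such genes, which shares no member with the cell cycle list, had a median log2 of 0.25 (0.19 to 0.35), with 46 above 0, 13 at least 1.5-fold higher and none 1.5-fold lower. Melk, a mitotic kinase, had 2.13 in Sham and 6.56 in TAC, Tpx2, a spindle assembly factor, 5.40 and 12.3, and Dlgap5 5.35 and 12.6. The licensing inhibitor Gmnn was lowest with 68.6 and 57.0, followed by Gins2 (27.5 and 22.9) and Mcm7 (82.7 and 70.5). Genes of replication were not read apart from those of mitosis. The median stood at percentile 100 of matched random lists, which is consistent with the hypothesis of a change across genes of mitosis and replication. The single genes named here, from Melk to Mcm7, were picked after their values were seen, while the test of the list of 61 was set down before.

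The higher NELF-A signal at cell cycle promoters was weighed against technical explanations. Counting error gave at most 1 cell cycle promoter 1.5-fold higher in 1000 draws, against 6 observed. A weaker enrichment in the TAC library, acting through signal level, would shift promoters of the same signal alike, yet the list's median of 0.24 lay above the range of matched random lists, -0.14 to 0.047. A larger share of leukocytes in TAC hearts cannot be told apart from a change in resident cells, since the leukocyte list has 8 promoters above the floor and a median of 0.14 with an interval from -0.30 to 0.71. Pressure overload itself stays open as well, and with 1 library of each kind so does any difference between the preparations.

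The lower signal at cardiomyocyte genes was weighed against counting error, weaker enrichment in the TAC library and a change in cell shares. Weaker enrichment acting through signal level would shift promoters of the same signal alike. Yet list medians lay below the ranges of matched random lists. The sarcomere list had -0.31 against -0.16 to 0.080, and cardiac transcription factors -0.33 against -0.12 to 0.043. Calcium and channel genes had -0.25 against -0.13 to 0.058, and fatty acid oxidation genes -0.24 against -0.11 to 0.036. These values argue against weaker enrichment for these lists, though the comparison was chosen after they were seen. Pooled over 98 promoters of the sarcomere, calcium and channel, fatty acid oxidation and cardiac transcription factor lists, the median was -0.29 (-0.34 to -0.23), with 91 below 0. Counting error gave a median no lower than -0.043 in 1000 draws. The pooled lists are the ones that stood at percentile 0, so a low pooled median follows in part from the choice of lists. Hypertrophy markers, at 0.012, and oxidative phosphorylation genes, at -0.077, were not pooled. A smaller share of cardiomyocytes in TAC hearts would raise all other markers alike only if the other cell types kept their proportions to each other. Those proportions were not measured, so a low smooth muscle list cannot decide about the share of cardiomyocytes. The full smooth muscle list stood at -0.35 and percentile 0.07. It holds Des and Abcc9, which cardiomyocytes also express and which were left out after that value was seen. The median over the other 9 genes was -0.15 (-0.46 to -0.10) at percentile 14.7, still below 0 but inside the matched range. A change in cell shares therefore cannot be told apart from a change within cardiomyocytes.

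Whether ion channel subunits beyond the fixed lists carry less NELF-A in TAC was asked of genes picked by symbol, among them Kcnk13 and Kcnn2, which are not voltage-gated. The 44 outside the fixed lists had a median of -0.093 (-0.26 to 0.037) at percentile 12.1, with 2 at least 1.5-fold higher, Kcnab2 highest (15.1 and 26.6), and 6 lower. This leaves out 11 channel genes of the fixed lists, Kcnip2 and Kcnh2 among them, so it does not decide about the family. With those 11, which was added after their values were seen, the median over 55 genes was -0.17 (-0.37 to -0.018) at percentile 0.47, and the question stays open.

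The authors' own class named for ratios of at least 1.5 holds 462 genes, with a lowest ratio of 1.37 at Nppa, and 237 of them (51.3%) lay under the Input floor in both libraries, with a class median of 2.21 in Sham. The class named for ratios of at most 0.75 holds 948 genes, with a highest ratio of 0.7505, a median of 14.8 in Sham and 227 under the floor. With 1 promoter for each gene, 231 promoters under the floor had a ratio of at least 1.5, against a median of 158 and at most 203 in 1000 draws from counting error. Above the floor there were 224, against a median of 24 and at most 42. Counting error alone therefore falls short of both counts, by a small margin under the floor and a wide one above it. The draws held no scatter from amplification or preparation, so such scatter was not tested as a source. No biological explanation was tested for this pattern either.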
